A study of Mus musculus with 10 samples.

How the data were processed

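RNA was measured by sequencing in 10 samples of sorted P14 CD8+ T cells, wild-type or lacking Batf, taken at day 0 or at day 3 after infection. Per the submitters' processing notes, RNA was extracted with a column kit, libraries were made with a commercial RNA kit, reads were examined with FastQC and trimmed with fastp, aligned with STAR to the mouse genome (GRCm38, also called mm10) and counted per gene with featureCounts, and StringTie is named as well. Versions, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap or that have near-identical copies (such as Ly6c1 and Ly6c2, Ifit3 and Ifit3b, or the protocadherin genes Pcdhgc3 and Pcdhgc4, which share exons) therefore carry uncertain values.

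The deposited values are counts of reads per gene, whole numbers without normalization, in a single table with 1 column per sample. The table held 35975 genes, of which 11437 had 0 counts in all samples. It also held 3 lines without a gene, which were left out. A further 27 symbols had been turned into dates by a spreadsheet program and could not be assigned to genes with certainty, so none of them is named. Symbols were shared by 4 lines, and 32500 symbols (90.3%) were found in the RefSeq gene table of assembly GRCm38.p6, from which coordinates were taken.

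Library totals ranged from 50914479 to 72711596 counts. A count of 0 in a library allows a level of up to 3 counts, which was 0.0413 CPM (counts scaled to library size) in the deepest library and 0.0589 in the shallowest. A fold against a group whose libraries were all at 0 is given as a lower bound, computed with 3 counts over the whole group. These limits cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. The bound on a fold takes the counts of the other group as exact, so the true fold may be lower where these counts are few.

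Samples were placed in 4 groups by genotype and day from their labels. Genes were filtered with filterByExpr, which left 17069 genes and set 18906 aside. A single quasi-likelihood model with a mean per group was fitted to the 10 libraries with edgeR 4.0.16 in R 4.3.3 (glmQLFit, robust, TMM scaling), which gave 6 residual degrees of freedom and a common biological coefficient of variation of 0.0842. There were 5 comparisons: the genotypes at day 3, the genotypes at day 0, the days in wild-type cells, the days in Batf-deficient cells, and the interaction of genotype and day. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene is called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors from the fit. Levels are CPM with TMM scaling, given as mean ± SD. Summed levels of markers are CPM of the library total.

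Gene lists numbered 31, of which 19 cover T-cell biology and 12 hold markers of other cells or technical checks. They held 518 genes, of which 512 were in the table. Lists were tested against all other genes with camera of limma 3.58.1 with a preset correlation of 0.01 between genes, and beside it with an estimated correlation and with fry, and adjusted over the 31 lists. Shares of counts were compared at day 3 with a two-sided exact permutation test of scipy 1.17.1, whose smallest p for 3 against 3 samples is 0.1. The relation between both changes over time was measured as a total least squares slope across genes. Tables were handled with pandas 2.3.3 in Python 3.11.15 and plots drawn with matplotlib 3.10.9.

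The comparisons, the tests, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, except where a choice is said to have been made later. By that rule the text names Batf, a panel of core genes, in each comparison up to 6 genes in each direction with the largest fitted change (among called genes with an average log2 CPM of at least 2 and no overlap between the groups, an overlap rule that the interaction does not use), and up to 4 members of each list with the smallest p plus the member that opposes the majority. Predicted and unnamed loci, receptor segments, sex-linked genes and genes with near-identical copies were left out of the ranking, although the protocadherin pair passed it and is not described, since reads of the shared exons cannot be assigned to either. Some genes that the rule would name are not reported here.

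The procedure was tested on simulated data with 200 changed genes in each comparison, drawn from genes with a simulated mean of at least 5 CPM. Recovery of sparser genes was not tested. Apart from the changed genes, no gene differed in the simulated comparison, and increases and decreases were equal in number. Scaling where many genes change, as in these data, was therefore not tested. For the genotypes at day 3 (16597 genes) it recovered 85.1% of genes changed by 1.5-fold, 94.0% of those changed by 2-fold and 97.0% of those changed by 4-fold, and called 11 unchanged genes. For the genotypes at day 0 (16520 genes) these shares were 85.1%, 95.5% and 100%, with 22 unchanged genes called. The change over time gave 97.0%, 98.5% and 100% in wild-type cells (16660 genes, 18 unchanged genes called) and 85.1%, 97.0% and 98.5% in Batf-deficient cells (16728 genes, 16 called). The interaction gave 71.6%, 91.0% and 98.5% (16623 genes, 23 called). A simulated slope of 0.8 came back as 0.798 when simulated levels were kept at or above 0.2 CPM (17048 genes) and as 0.699 without that floor (16620 genes), so genes near 0 pull the slope.

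Alternatives were size factors of the DESeq2 type, library size alone, upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter at a mean of 50 counts, a fit of only the groups compared, a block for the replicate number, leaving out each of the 10 libraries in turn, an adjusted p under 0.01, and a change of at least 2-fold. Chosen after seeing the data were a restriction to genes with a mean of at least 5 CPM at day 3, a scaling to the T-cell identity genes, the slopes over genes that rose and over genes of at least 5 CPM at day 3, 200 random swaps of the genotypes of each gene before these slopes were taken, and a fit that splits the wild-type libraries of day 3 into 1 and 2. A planned share of counts from the most used T-cell receptor segment was not computed, because the table holds 0 receptor segment genes. Data of other assays of the study were not analysed here.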

Results

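Gene expression was measured by RNA sequencing in P14 CD8+ T cells, which carry a transgenic T-cell receptor for an epitope of the glycoprotein of lymphocytic choriomeningitis virus (LCMV). The cells were wild-type or lacked Batf, a transcription factor of the AP-1 family that binds DNA together with IRF4. They were sorted by flow cytometry as naive cells (day 0) or at day 3 after infection with the Armstrong strain, which causes an acute infection. There were 2 wild-type and 2 Batf-deficient samples at day 0, and 3 wild-type and 3 Batf-deficient samples at day 3. Total counts were 57646168 and 50914479 in the wild-type and 53060089 and 55504910 in the Batf-deficient libraries of day 0. At day 3 they were 71592156, 64576388 and 64107842 in the wild-type and 72711596, 53115375 and 53297514 in the Batf-deficient libraries. The labels do not say whether the samples come from separate animals, so p-values measure the spread between these samples. Log2 levels of replicates correlated at r of 0.994 to 0.997 across genes, which are not independent replicates. The first principal component held 86.4% of the variance and parted the days, and the second held 4.97% and parted the genotypes at day 3.

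**Figure D1:**
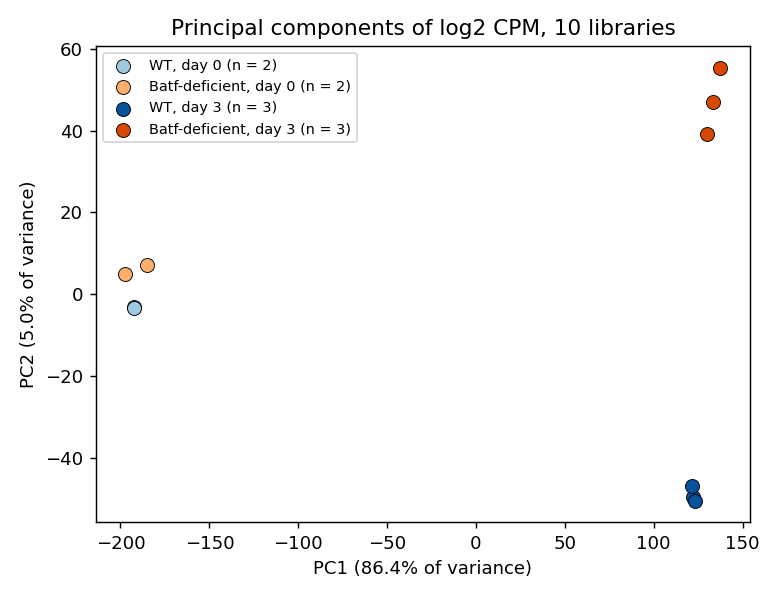
Principal components of log2 CPM in the 10 libraries, 1 point per library, with axes in component units. The first component (86.4% of the variance) parts day 0 from day 3, and the second (4.97%) parts the genotypes at day 3.

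Batf transcripts were nearly absent from Batf-deficient cells. Batf lies on chromosome 12 at 85686720 to 85709087 on the plus strand (GRCm38.p6) and has 3 exons. Its counts were 1720 and 1288 in the wild-type and 10 and 1 in the Batf-deficient libraries of day 0. At day 3 they were 4741, 4090 and 3875 in the wild-type and 133, 74 and 65 in the Batf-deficient libraries. The level at day 3 was 64.9 ± 2.68 CPM in wild-type and 1.55 ± 0.326 CPM in Batf-deficient cells (SD, n = 3), a log2 fold change of -5.36 (SE 0.15, adjusted p = 3.35e-13 by edgeR). At day 0 it was 25.5 ± 2.95 against 0.0987 ± 0.114 CPM (SD, n = 2), a log2 fold change of -7.99 (SE 0.28, adjusted p = 3.15e-11 by edgeR). Which part of the gene was removed is not given in the sources used here. Of 21 measured genes beside Batf, 7 were higher, 6 lower and 8 not called at day 3, and 0 were higher, 3 lower and 18 not called at day 0. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were expressed in all 10 libraries.

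The comparison at day 3 asks which parts of the effector program depend on Batf once cells have met the virus. Batf-deficient cells had less Itga4, which encodes the alpha-4 integrin used to enter inflamed tissue, at 66.9 ± 12.6 CPM against 508 ± 29.9 CPM in wild-type cells (SD, n = 3). Tcf7, which encodes a transcription factor of naive and memory cells, was higher, at 656 ± 33.6 against 246 ± 22.2 CPM. Cytotoxic molecules were higher: Gzmb was at 5010.0 ± 329 against 3430.3 ± 90.9 CPM, and Prf1, which encodes the pore-forming protein perforin, at 459 ± 23.7 against 167 ± 8.31 CPM. Genes for DNA replication were lower. All 20 ribosome assembly genes were lower and all 23 measured interferon-stimulated genes higher, but neither list passed with an estimated correlation (adjusted p = 0.128 and 0.159 with an estimated correlation). With fry, which does not compare a list with other genes, both had an adjusted p = 1.41e-05. Fry also called lists that camera did not, such as effector transcription factors (adjusted p = 0.00153 with fry, 0.391 with camera). With edgeR, 7820 of 17069 genes were called, 3960 higher and 3860 lower, and 1805 of them differed by at least 2-fold (839 higher, 966 lower). The share that was higher was 50.6%, against 11.5% with a scaling to T-cell identity genes, chosen after the data were seen. That scaling moves all genes alike, by a median of -0.51 here, and its own genes were higher in 10 of 11 members, so the direction of increases smaller than this depends on the scaling. Some larger increases keep their direction with it but lose their call.

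Among core effector genes, Il12rb2, which encodes a subunit of the interleukin 12 receptor, was 2.22-fold lower in Batf-deficient cells at day 3 (38.9 ± 5.30 against 86.3 ± 3.06 CPM, SD, n = 3, edgeR adjusted p = 2.57e-09). Tbx21, which encodes the effector regulator T-bet, differed less, with a log2 fold change of -0.22 (SE 0.06, edgeR adjusted p = 0.00501). Irf4, whose protein pairs with BATF on DNA, was higher by 0.64 (SE 0.06, edgeR adjusted p = 8.74e-08), at 161 ± 10.7 against 103 ± 8.16 CPM. Ifng, which encodes interferon gamma, was 2.01-fold higher (74.5 ± 2.07 against 37.1 ± 7.61 CPM, edgeR adjusted p = 8.69e-07). Gzmb was higher by 0.55 and Prf1 by 1.46 (SE 0.06 for each, edgeR adjusted p = 2.18e-07 and 1.98e-12). Tcf7 was higher by 1.41 (SE 0.07, edgeR adjusted p = 1.02e-10), and Itga4 was lower, with a log2 fold change of -2.92 (SE 0.13, edgeR adjusted p = 1.21e-07). Il7r, Id3 and Klrg1 were higher by 0.80, 0.77 and 0.99. With the scaling to T-cell identity genes, Irf4, Gzmb, Il7r and Id3 were no longer called. Eomes, Prdm1 and Il2ra were not called (edgeR adjusted p = 0.642, 0.0787 and 0.137). Id2 was called at -0.20 (edgeR adjusted p = 0.0149), but not without Batf-deficient replicate 2, wild-type replicate 1 or wild-type replicate 3 of day 3. Itga4 lies on chromosome 2 at 79255426 to 79333114, Tcf7 on chromosome 11 at 52246527 to 52283383 and Il12rb2 on chromosome 6 at 67285986 to 67376293 (GRCm38.p6).

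**Figure D2:**
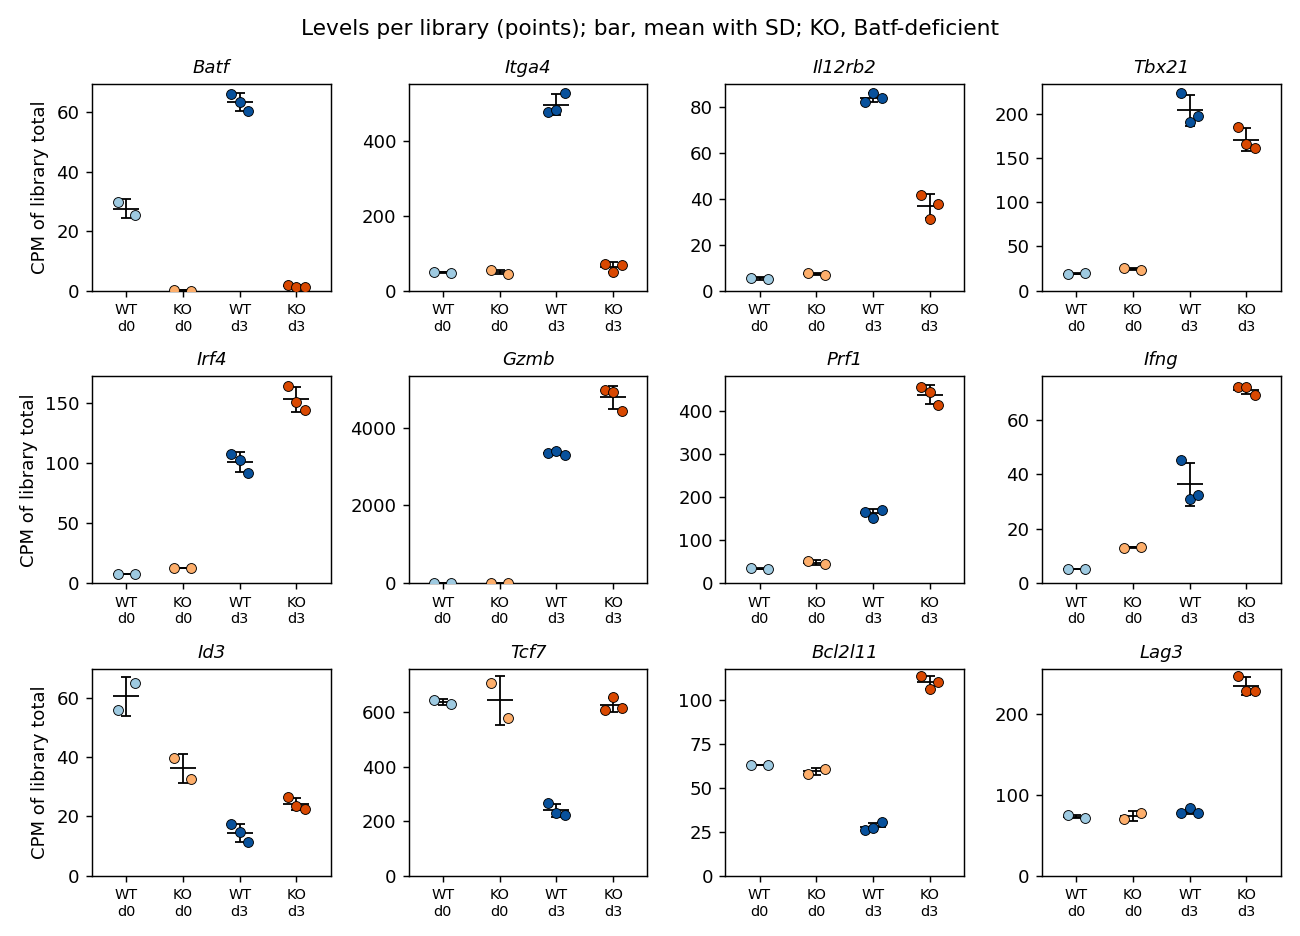
Levels of 12 genes in CPM of the library total, 1 point per library with the mean and SD of each group. Batf-deficient cells of day 3 had less Batf, Itga4 and Il12rb2 and more Tcf7, Prf1, Bcl2l11 and Lag3 than wild-type cells.

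Cytotoxic effector molecules as a list had 14 members higher, 2 lower and 4 not called at day 3 (15 higher and 2 lower when adjusted over the list alone). Srgn, which packs granules, was higher by 1.28 and the chemokine gene Ccl4 by 2.42 on the log2 scale (93.8 ± 10.1 against 17.6 ± 2.98 CPM), while the granzyme inhibitor Serpinb9 had a log2 fold change of -0.44. The list test gave an adjusted p = 1.52e-06, and an adjusted p = 0.0417 with an estimated correlation. Of the naive and memory-precursor genes, 16 were higher, 2 lower and 4 not called, with Actn1 higher by 1.27 and Socs3, an inhibitor of cytokine signals, by 1.70 (adjusted p = 4.84e-07, and adjusted p = 0.0343 with an estimated correlation). Cytokine receptor genes had 12 members higher, 3 lower and 3 not called, with Il4ra at 148 against 51.4 CPM and Ifnar1 at 223 against 103 CPM (adjusted p = 0.000295, and adjusted p = 0.0417 with an estimated correlation). Genes of the AP-1 and IRF family had 13 higher, 4 lower and 6 not called, among them Irf8 higher by 1.08, Junb higher by 0.86 and Mafg at -0.98 (adjusted p = 0.018, and adjusted p = 0.359 with an estimated correlation). Effector transcription factors had 7 higher and 6 lower (adjusted p = 0.391), among them Stat4 higher by 0.52 and Rora at -0.63. Inhibitory receptors had 6 higher and 5 lower (adjusted p = 0.726), with Lag3 at 246 ± 10.7 against 81.3 ± 4.66 CPM and Havcr2, which encodes TIM-3, at 77.4 against 135 CPM. Chemokine receptors and adhesion molecules had 10 higher and 6 lower (adjusted p = 0.254, median 0.29 and mean -0.26), with Cxcr3 higher by 0.63. T-cell activation genes had 7 higher, 3 lower and 8 not called (adjusted p = 0.436), with Cd69 higher by 1.78 and Icos at -0.87.

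Many genes of growth and division were lower in Batf-deficient cells at day 3. All 20 genes of DNA replication were lower (median log2 fold change -0.55), with the helicase gene Mcm2 at 311 against 501 CPM and Rrm2, which makes deoxynucleotides, at 520 against 867 CPM (adjusted p = 9.62e-13, and adjusted p = 0.0343 with an estimated correlation). Of 20 mitosis genes, 13 were lower, 1 was higher and 6 were not called, with Ccnb1 at -0.52 and Mki67 at -0.42 (adjusted p = 0.000735, and adjusted p = 0.166 with an estimated correlation). The higher member was Ccnb2 by 0.15, not called in 6 of 10 fits without 1 library, nor with the other 3 scalings, the other 2 filters or DESeq2. All 20 genes of ribosome biogenesis were lower (median -0.89), with Nolc1 at 115 against 251 CPM and Fbl, which methylates ribosomal RNA, at 151 against 281 CPM (adjusted p = 1.99e-16, and adjusted p = 0.128 with an estimated correlation). Amino acid transport and one-carbon metabolism had 0 higher, 12 lower and 3 not called, with Mthfd1 at 78.1 against 152 CPM and Slc7a1 at -0.92 (adjusted p = 2.44e-07, and adjusted p = 0.209 with an estimated correlation). Glycolysis had 4 higher, 10 lower and 6 not called, with Tpi1 at 187 against 415 CPM and Pdk1 higher by 0.41 (adjusted p = 0.0082, and adjusted p = 0.259 with an estimated correlation). Sterol and fatty acid synthesis had 1 higher, 10 lower and 9 not called, with Fasn at 223 against 406 CPM and Scd1, a desaturase gene, at 0.843 ± 0.228 against 6.21 ± 0.529 CPM (adjusted p = 0.0121, and adjusted p = 0.473 with an estimated correlation). Oxidative phosphorylation and the TCA cycle had 2 higher, 12 lower and 13 not called, with Cyc1 at -0.54 (adjusted p = 0.0253, and adjusted p = 0.473 with an estimated correlation), and this call was lost without Batf-deficient replicate 3 or without wild-type replicate 1 of day 3. Mitochondrially encoded genes had 0 higher, 9 lower and 4 not called, with ND1 at -1.17 and ND5 at -1.07 (adjusted p = 0.00034, and adjusted p = 0.473 with an estimated correlation). Their share of counts was 0.432 ± 0.0443% against 0.815 ± 0.0969% (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). With fry, the adjusted p was 0.000109 for mitosis, 4.86e-05 for glycolysis and 0.00278 for mitochondrially encoded genes.

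Interferon-stimulated genes were higher in Batf-deficient cells at day 3 in 23 of 23 measured members (median 1.33), with Zbp1, a sensor of nucleic acids, at 399 against 129 CPM and Ifi27l2a at 961 against 261 CPM (adjusted p = 9.89e-22, and adjusted p = 0.159 with an estimated correlation). Gbp2 was at 172 against 45.9 CPM and Oas1a at 159 against 45.7 CPM. T-cell identity genes had 10 higher and 1 not called, with Cd3d at 521 against 264 CPM and Cd8a at 1340.6 against 860.4 CPM (adjusted p = 7.51e-08, and adjusted p = 0.112 with an estimated correlation). B-cell markers moved the other way, with 11 lower and 2 higher (median -2.80, Cd79b higher by 0.60), and H2-Ab1 was at 1.49 against 13.1 CPM (adjusted p = 1.33e-07, and adjusted p = 0.166 with an estimated correlation). Markers of the stromal and endothelial list summed to 86.2 ± 3.58 against 34.1 ± 1.59 CPM with 1 member higher and 1 lower, and the lists of monocytes, dendritic cells, CD4 T cells, natural killer cells and erythroid cells did not pass (adjusted p = 0.511, 0.559, 0.774, 0.774 and 0.372).

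Genes that control cell death moved both ways, with 8 higher, 7 lower and 6 not called (adjusted p = 0.391, median -0.02 and mean 0.17). Bcl2l11, which encodes the death-promoting protein BIM, was at 116 ± 2.95 against 28.6 ± 2.49 CPM (SD, n = 3), higher by 2.01 on the log2 scale (SE 0.06, edgeR adjusted p = 1.20e-13). Bbc3, which encodes PUMA, was at 15.7 against 3.83 CPM, and the survival gene Bcl2a1d was lower at -1.52. Chromatin regulators had 5 higher, 12 lower and 8 not called (adjusted p = 0.0905), with Ezh2 at -0.57, Hdac2 at -0.75 and Hdac7 higher by 0.62. Genes of other helper and regulatory programs had 3 higher, 6 lower and 5 not called (adjusted p = 0.551), with Il10 at 22.4 against 6.16 CPM, Bcl6 higher by 1.14 and Tgfbr3 at -2.45. Immediate-early and heat-shock genes had 6 higher, 2 lower and 7 not called (adjusted p = 0.22), with Dusp1 higher by 1.30 and Hsp90aa1 at 803 ± 25.9 against 1935 ± 184 CPM. The largest fitted changes were in sparse transcripts. Ltf and Igfbp7 had 0 counts in wild-type cells of day 3 and 44 and 14 counts in Batf-deficient cells. With these counts taken as exact, they were at least 16.4-fold and 5.22-fold higher. Ltf is a gene of neutrophils, as are S100a8, at 0.67 against 0.0201 CPM, and Ngp, at 0.457 against 0.0319 CPM, and 8 genes of this class summed to 2.83 against 0.528 CPM. Ago4 and Krt80 had 0 counts in Batf-deficient cells of day 3 and 34 counts each in wild-type cells. With these counts taken as exact, they were each at least 10.1-fold lower. Osgin1 was at 12.5 against 1.06 CPM and Ifitm1 at 7.87 against 0.70 CPM.

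**Figure D3:**
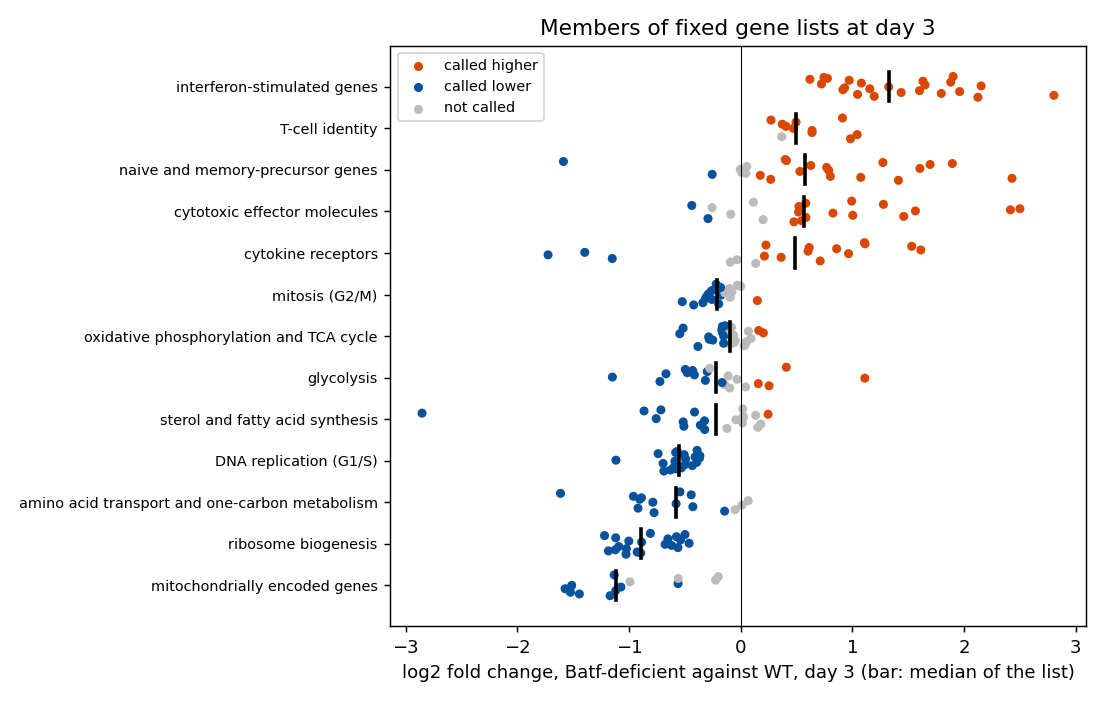
Log2 fold change of Batf-deficient against wild-type cells at day 3 for the members of 13 gene lists, 1 point per gene with the median as a bar. The medians were 1.33 for interferon-stimulated genes, -0.55 for DNA replication and -0.89 for ribosome biogenesis.

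The comparison at day 0 asks whether naive cells already differ without Batf. Transcripts of neutrophils were higher in Batf-deficient samples, with S100a8 at 209 ± 18.3 against 9.58 ± 1.003 CPM and Ngp at 171 ± 4.62 against 7.15 ± 0.379 CPM (SD, n = 2). Ctrb1, which encodes a digestive enzyme of the pancreas, was at 46.1 ± 5.79 against 2.29 ± 0.203 CPM. These genes mark other cell types, so their values are not read as a difference between naive T cells. Cell-cycle genes and cytotoxic genes were higher as well. Interferon-stimulated genes were higher in 21 of 23 members, but the list did not pass with an estimated correlation (adjusted p = 0.081 with an estimated correlation). It passed with fry (adjusted p = 0.000485). With edgeR, 3060 genes were called, 1635 higher and 1425 lower, and 467 differed by at least 2-fold (368 higher, 99 lower). The count was 1590 without wild-type replicate 1 and also 1590 without wild-type replicate 2 of day 0. The share of called genes that were higher was 53.4%, against 36.1% with library size alone and 69.7% with a scaling to T-cell identity genes.

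Both genotypes of day 0 held transcripts of other cell types. Summed markers of monocytes, macrophages and neutrophils were 7426.3 ± 155 CPM in wild-type and 6786.4 ± 482 CPM in Batf-deficient samples of day 0 (SD, n = 2), and 99.6 and 91.1 CPM at day 3. B-cell markers summed to 1953.3 ± 8.92 CPM in wild-type and 3935.5 ± 422 CPM in Batf-deficient samples of day 0. B-cell markers had 11 higher, 0 lower and 2 not called (adjusted p = 6.11e-11, and adjusted p = 0.081 with an estimated correlation), with Cd79a higher by 1.47 and H2-Ab1 at 630.3 against 286 CPM. Natural killer markers had 6 higher and 2 not called (adjusted p = 0.000722, and adjusted p = 0.0515 with an estimated correlation). Erythroid markers had 4 higher and 9 not called (adjusted p = 0.000722, and adjusted p = 0.167 with an estimated correlation), and markers of dendritic cells 1 higher and 6 not called (adjusted p = 0.00579, and adjusted p = 0.081 with an estimated correlation). The list of monocyte, macrophage and neutrophil markers had 5 higher, 4 lower and 7 not called, with a median of -0.02 and a mean of 0.88 (adjusted p = 0.0128, and adjusted p = 0.354 with an estimated correlation), and this call was lost without either Batf-deficient replicate or without wild-type replicate 1 of day 0.

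Beside these markers, mitosis genes at day 0 were higher in 20 of 20 members (median 0.74), with the spindle gene Tpx2 at 22.3 against 11.5 CPM and Birc5 higher by 0.95 (adjusted p = 1.36e-29, and adjusted p = 0.00515 with an estimated correlation). DNA replication had 15 higher and 5 not called, with Rrm2 at 46.8 against 23.0 CPM (adjusted p = 1.16e-12, and adjusted p = 0.0197 with an estimated correlation). Cytotoxic molecules had 15 higher, 1 lower and 4 not called, with Gzma at 235 against 86.9 CPM and Gzmb at 17.4 ± 1.53 against 8.84 ± 0.809 CPM (adjusted p = 1.54e-14, and adjusted p = 0.00687 with an estimated correlation). The lower member was Gzmk at -0.73, not called without either Batf-deficient replicate or wild-type replicate 1 of day 0, with limma-voom, or with only the groups compared. Interferon-stimulated genes had 21 higher and 2 not called, with Zbp1 at 131 against 59.0 CPM and Usp18 higher by 1.39 (adjusted p = 3.15e-27, and adjusted p = 0.081 with an estimated correlation). Cytokine receptors had 8 higher, 1 lower and 9 not called, with Il18rap higher by 1.03 (adjusted p = 0.00047, and adjusted p = 0.0424 with an estimated correlation). Glycolysis had 3 higher and 17 not called (adjusted p = 0.0222, and adjusted p = 0.354 with an estimated correlation), and oxidative phosphorylation 8 higher, 1 lower and 18 not called (adjusted p = 0.00579, and adjusted p = 0.362 with an estimated correlation), and both calls were lost with library size alone. Chemokine receptors and adhesion molecules had 7 higher, 2 lower and 12 not called (adjusted p = 0.0699), with Ly6c2 at 472 against 117 CPM. Naive and memory-precursor genes had 4 higher, 2 lower and 16 not called (adjusted p = 0.736), and T-cell identity genes 0 higher, 2 lower and 9 not called (adjusted p = 0.134). Mitochondrially encoded genes had 0 called members and 13 not called, although the list passed (adjusted p = 0.0255, and adjusted p = 0.615 with an estimated correlation), a call lost with fry and without Batf-deficient replicate 2 or wild-type replicate 2 of day 0.

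Core genes at day 0 included Ifng at 12.8 ± 0.445 against 4.75 ± 0.0266 CPM (SD, n = 2), higher by 1.43 (SE 0.15). Irf4 was higher by 0.79, Klrg1 by 1.62, Prf1 by 0.58 and Eomes by 0.49. In the same samples the lists of natural killer and B-cell markers had medians of 0.98 and 1.13 on the log2 scale. Whether other cells contributed to the values of core genes was not tested. Prdm1, Tcf7, Il7r and Id2 were not called. Calls that leaving out 1 library of day 0 ended were those of Tbx21 (0.40, lost without wild-type replicate 1), Il12rb2 (0.52, without wild-type replicate 2), Il2ra (0.67, without wild-type replicate 1 or Batf-deficient replicate 2) and Id3 (-0.67, without replicate 2 of either genotype). Il12rb2 and Il2ra were not called with limma-voom either, nor Il2ra with only the groups compared. Among the largest decreases, the stress-response gene Ddit4 was at 54.6 ± 0.597 against 139 ± 0.784 CPM, Lmbrd2 at 2.96 against 9.51 CPM, and Mid1, which encodes a ubiquitin ligase, at 1.502 ± 0.118 against 5.50 ± 0.273 CPM.

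The change from day 0 to day 3 asks how far cells respond to the infection with and without Batf. Gzmb rose from 8.84 to 3430.3 CPM in wild-type and from 17.4 to 5010.0 CPM in Batf-deficient cells, by 8.60 and 8.17 on the log2 scale (SE 0.10 and 0.09). Il2ra, which encodes the alpha chain of the interleukin 2 receptor, rose by 6.39 and 5.85, and Zbtb32, which encodes a zinc-finger repressor, by 7.70 and 6.54. Irf4 rose by 3.84 and 3.69, Tbx21 by 3.54 and 2.92, Prdm1 by 2.28 and 2.06, Ifng by 2.97 and 2.55, and Prf1 by 2.42 and 3.30. Il12rb2 rose by 4.11 in wild-type and by 2.45 in Batf-deficient cells. With edgeR, 13025 genes were called in wild-type cells, 5800 higher and 7225 lower (44.5% higher), and 12916 in Batf-deficient cells, 6018 higher and 6898 lower (46.6% higher). Changes of at least 2-fold numbered 7957 and 7424. The median log2 fold change of all genes was -0.18 in wild-type and -0.12 in Batf-deficient cells, and with a scaling to T-cell identity genes it was -0.59 and -1.10, with 29.9% and 12.1% of called genes higher. This is a shift of all genes alike, by -0.41 and -0.97, and the identity genes themselves rose in 7 and 11 of 11 members. The day 0 libraries held transcripts of other cell types that were nearly gone at day 3. How far their loss raised the values of T-cell genes was not tested.

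In wild-type cells Tcf7 fell by 1.26, Il7r by 2.78 and Id3 by 1.91 on the log2 scale. In Batf-deficient cells Il7r fell by 1.97 and Id3 by 0.47, and Tcf7 was not called (0.08, edgeR adjusted p = 0.367). With the scaling to T-cell identity genes, the Tcf7 value there was -0.90. Eomes rose by 0.39 and Klrg1 by 0.56 in Batf-deficient cells. The rise of Eomes was not called without Batf-deficient replicate 2 of day 0, that of Klrg1 not without the same library or Batf-deficient replicate 1 of day 3 (upper-quartile scaling ended both, and a filter at 50 counts or a fit of only the groups compared that of Klrg1), and the Id2 change of -0.19 not without Batf-deficient replicate 2 of day 3. Both genotypes raised all 20 mitosis genes (median 4.599 and 3.70) and all 20 DNA replication genes (median 3.45 and 2.68), with Mki67 up by 4.90 and 3.81 and Uhrf1 by 4.62 and 3.48. The mitosis list gave an adjusted p = 5.99e-28 in wild-type cells, and an adjusted p = 0.00595 with an estimated correlation. Cytotoxic molecules had 16 higher and 3 lower in wild-type cells (adjusted p = 1.18e-05, and adjusted p = 0.0388 with an estimated correlation) and 18 higher and 1 lower in Batf-deficient cells (adjusted p = 1.21e-09, and adjusted p = 0.00821 with an estimated correlation). Gzmk rose by 6.55 and 6.98, Gzma by 4.21 and 3.26, while Lamp1 fell by 2.14 and 2.01. Markers of splenic macrophages fell from 9387.6 to 2.16 CPM in wild-type and from 7052.8 to 1.54 CPM in Batf-deficient libraries. Their part in the fall of Lamp1 was not tested. Naive and memory-precursor genes had 5 higher and 14 lower in wild-type cells (adjusted p = 0.00082, and adjusted p = 0.066 with an estimated correlation) and 7 higher and 10 lower in Batf-deficient cells (adjusted p = 0.265).

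Ribosome biogenesis genes had 19 higher and 1 lower in wild-type cells (adjusted p = 1.18e-05, and adjusted p = 0.24 with an estimated correlation), and 8 higher, 8 lower and 4 not called in Batf-deficient cells (adjusted p = 0.972). Ddx21, which acts in ribosomal RNA processing, rose by 1.67 and 0.88, and Bop1 rose by 0.73 in Batf-deficient cells. Glycolysis genes had 17 higher and 2 lower in wild-type cells (adjusted p = 1.09e-08, and adjusted p = 0.0388 with an estimated correlation) and 17 higher and 3 lower in Batf-deficient cells (adjusted p = 1.5e-06, and adjusted p = 0.0641 with an estimated correlation), with Pgk1 up by 2.12 and 1.57. Sterol and fatty acid synthesis had 19 higher and 0 lower (adjusted p = 4.72e-09, and adjusted p = 0.0821 with an estimated correlation) and 19 higher and 1 lower, Scd1 (adjusted p = 2.27e-06, and adjusted p = 0.124 with an estimated correlation). Amino acid transport and one-carbon metabolism had 14 higher and 1 lower in wild-type cells (adjusted p = 1.13e-08, and adjusted p = 0.126 with an estimated correlation), and 13 higher and 2 lower in Batf-deficient cells (adjusted p = 0.000105, and adjusted p = 0.244 with an estimated correlation), with Psat1 up by 3.56 and 2.33. Interferon-stimulated genes had 9 higher and 11 lower in wild-type cells (adjusted p = 0.584) and 16 higher and 3 lower in Batf-deficient cells (adjusted p = 0.00922, and adjusted p = 0.566 with an estimated correlation). Inhibitory receptor genes had 8 higher, 4 lower and 3 not called in wild-type cells (adjusted p = 0.085), and 9 higher, 4 lower and 2 not called in Batf-deficient cells (adjusted p = 0.0274, and adjusted p = 0.245 with an estimated correlation), a call also lost without Batf-deficient replicate 1 of day 0. Among them Pdcd1 rose by 4.45 and 4.37 and Ctla4 by 4.16 and 3.12.

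The largest decreases were in genes of macrophages and platelets, whose markers were nearly gone at day 3. Adamdec1 had 0 counts at day 3 and was at least 10861-fold lower in wild-type and at least 9630-fold lower in Batf-deficient libraries. Marco, a scavenger receptor gene, was at least 8737-fold lower in wild-type and Mrc1 at least 20709-fold lower in Batf-deficient libraries. Hpgd had 2 counts at day 3 in wild-type libraries, a ratio of 49952 (95% counting interval 13827 to 412477). Erythroid and platelet markers were lower in 13 of 13 members in both genotypes (adjusted p = 8.7e-15 in wild-type, and adjusted p = 0.0248 with an estimated correlation). The wild-type list of monocyte, macrophage and neutrophil markers had 14 lower and 2 higher (adjusted p = 1.9e-10, and adjusted p = 0.0388 with an estimated correlation), with C1qa at -12.85.

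The interaction asks whether the change from day 0 to day 3 differed between the genotypes. Itga4 gained less without Batf, with an interaction of -3.03 on the log2 scale (SE 0.21), as did Il12rb2 at -1.67 and Tbx21 at -0.62. Id3 (1.44), Tcf7 (1.33) and Prf1 (0.88) ended higher without Batf than the wild-type change would give. Bcl2l11 (2.03), Bbc3 (2.43) and Lag3 (1.51) did so as well, and Gzmb went the other way at -0.42, a call lost with limma-voom. Each of these values includes the genotype difference at day 0, where the part of other-cell RNA was not tested. Irf4, Prdm1, Ifng, Id2 and Klrg1 were not called, with -0.15 for Irf4 (edgeR adjusted p = 0.314) and -0.42 for Ifng (edgeR adjusted p = 0.0882). With edgeR, 6197 genes were called, 3134 higher and 3063 lower (50.6% higher), and 1749 at 2-fold or more. Scaled to T-cell identity genes, which moves all genes by -0.56, 8447 genes were called and 8.52% were higher. Eomes (-0.43) was not called without either wild-type replicate or Batf-deficient replicate 1 of day 0, Il2ra (-0.54) without wild-type replicate 1 or Batf-deficient replicate 2 of day 0 or with limma-voom. Il7r (0.82) was not called without either wild-type replicate or Batf-deficient replicate 2 of day 0, or without Batf-deficient replicate 1 of day 3.

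By list, the interaction was negative in 20 of 20 genes of mitosis (median -0.94), of DNA replication (median -0.95) and of ribosome biogenesis. Examples were Tpx2 at -1.19, Rrm2 at -1.76 and Dkc1 at -1.62. Mitosis and DNA replication passed with an adjusted p = 0.0106 with an estimated correlation, and ribosome biogenesis had an adjusted p = 0.115 with an estimated correlation. The mitosis and DNA replication lists were higher without Batf at day 0 (median 0.74 and 0.40) and lower at day 3 (median -0.21 and -0.55). At day 3 mitosis fell short (adjusted p = 0.166 with an estimated correlation), and at day 0 transcripts of B cells, natural killer cells and neutrophils were higher in Batf-deficient samples too. Naive and memory-precursor genes had 15 higher, 3 lower and 4 not called (adjusted p = 3.20e-06, and adjusted p = 0.032 with an estimated correlation), with Actn1 at 1.68. Interferon-stimulated genes had 15 higher, 0 lower and 8 not called (adjusted p = 7.49e-06, and adjusted p = 0.451 with an estimated correlation), with Gbp2 at 1.14. Cytotoxic molecules had 6 higher, 6 lower and 8 not called (adjusted p = 0.998), with Serpinb9 at -1.13 and Gzma at -0.96. Amino acid transport and one-carbon metabolism had 1 higher and 11 lower (adjusted p = 7.58e-07, and adjusted p = 0.291 with an estimated correlation), with the asparagine synthetase gene Asns at -2.95. B-cell markers had 0 higher and 11 lower (adjusted p = 7.26e-13, and adjusted p = 0.0931 with an estimated correlation) and moved in the same direction as the growth lists.

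Across the 14746 genes called in either genotype, the change in Batf-deficient cells followed that in wild-type cells with a slope of 1.05 (r = 0.908). These genes include transcripts of other cells that fell in both genotypes, such as C1qa. Both changes share no library, and genes are not independent replicates. Over the 6979 genes that rose in either genotype, a choice made after the data were seen, the slope was 0.782 (r = 0.665). With the genotypes of each gene swapped at random before genes were chosen, it lay between 0.926 and 1.09 over rising genes and between 0.986 and 1.02 over genes called in either genotype (200 swaps). Swapping makes the genotypes alike by construction (mean slope 1.003 over rising genes). The swaps thus test only whether the choice of genes moves the slope, and give no spread between libraries. The slope over rising genes was not taken with libraries left out. Of the genes called in both genotypes, 10659 changed in the same direction and 536 in opposite directions, while 1830 were called in wild-type and 1721 in Batf-deficient cells alone. Of 5800 genes that rose in wild-type cells, 2355 were lower in Batf-deficient cells at day 3, among them Itga4, Il12rb2 and Mcm2, against 1312 if the calls were independent, while 1182 were higher, against 1346. Likewise, 2063 of the 7225 that fell were higher, among them Tcf7, against 1676. The independent numbers take no account of level, and genes with few counts at day 3 are harder to call in either direction. The size of the excess is therefore not read from them. Of the genes that rose, 2355 were called lower and 1182 higher, while over all genes tested 3860 were called lower and 3960 higher. The wild-type libraries of day 3 serve in both comparisons. When they were split so that no library was shared, a choice made after the data were seen, the number of genes that rose and were lower was 1.83 to 1.93 times the independent number over the 6 splits, against 1.80 with shared libraries. The split leaves the part of level in place.

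**Figure D4:**
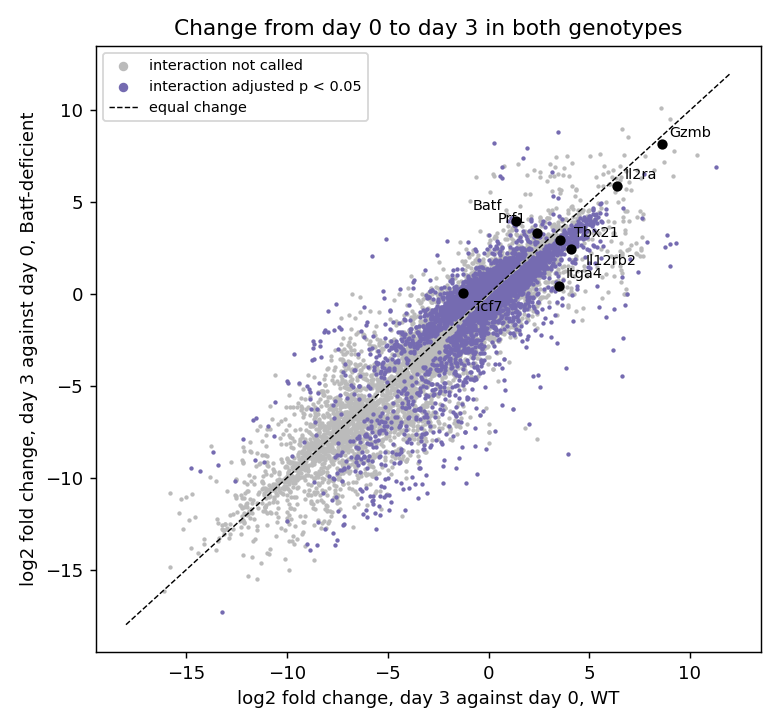
Fitted log2 fold change from day 0 to day 3 in wild-type (horizontal) and Batf-deficient cells (vertical), 1 point per gene, with purple points for the 6197 genes whose interaction was called and a dashed line of equal change. Gzmb lies at 8.60 and 8.17 and Il12rb2 at 4.11 and 2.45.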

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

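Chosen only after the results were seen were the tests of other-cell RNA, of library size and of a single abundant mitochondrial transcript. The tests of normalization, of GC content and length, and of other splits of the samples were written before.

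Several core genes differed between the genotypes by another amount at day 3 than at day 0, as tested by the interaction in edgeR. The log2 difference was 2.63 for Batf (adjusted p = 0.000258), -0.62 for Tbx21 (9.51e-05), -0.43 for Eomes (0.0185), -0.42 for Gzmb (0.00285), 0.88 for Prf1 (1.05e-06), 1.33 for Tcf7 (1.02e-07), 0.82 for Il7r (0.0173), 1.44 for Id3 (6.21e-05), -0.54 for Il2ra (0.0209) and -1.67 for Il12rb2 (1.40e-07). The calls of Eomes, Il2ra and Il7r were lost without single libraries, and those of Gzmb and Il2ra with limma-voom. For Batf, the value rests on the 10 counts and 1 count left in Batf-deficient samples of day 0. Lists that differed in the interaction, as tested by camera with a preset correlation, were naive and memory-precursor genes (adjusted p = 3.20e-06), DNA replication and mitosis (4.06e-18 each), glycolysis (0.000261), oxidative phosphorylation (0.000407), amino acid transport and one-carbon metabolism (7.58e-07), sterol and fatty acid synthesis (0.00458), ribosome biogenesis (6.11e-17), interferon-stimulated genes (7.49e-06), T-cell identity (1.95e-08), B-cell markers (7.26e-13) and mitochondrially encoded genes (3.07e-05). With an estimated correlation, naive and memory-precursor genes (adjusted p = 0.032), DNA replication and mitosis (0.0106 each) kept their calls and the others did not. All of these lists passed with fry (highest adjusted p = 0.0109, for interferon-stimulated genes). Mitosis genes had a median of 0.74 at day 0 and -0.21 at day 3, and DNA replication genes 0.40 and -0.55. Other-cell RNA in the day 0 samples may bear on the day 0 part of both, which was not tested.

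Interferon-stimulated genes summed to 4214.6 CPM in Batf-deficient and 1677.1 CPM in wild-type libraries of day 3. The 68 other-cell markers at day 3 summed to 430 ± 29.0 CPM in Batf-deficient and 436 CPM in wild-type libraries, against 2538 CPM added to the list. Their sum sets no upper limit on RNA of other cells. It also joins B-cell markers at 124 against 167 CPM with stromal and endothelial ones at 86.2 against 34.1 CPM. The markers as a whole did not rise with the list, but the test does not exclude RNA of other cells. Normalization is argued against for 4 scalings, since the lowest median of the list over them was 1.27. The scaling to T-cell identity genes was not among them. It moves all genes by -0.51 for the genotypes at day 3, a shift smaller in size than the list median of 1.33 with TMM scaling. At day 0 other-cell markers were 1.16 times as high in Batf-deficient samples, so RNA of other cells stays open there too. A biological effect of Batf loss may underlie the day 3 part, as a hypothesis from the same data. The list fell short with an estimated correlation and passed with fry (adjusted p = 1.41e-05).

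Mitochondrially encoded genes were lower in Batf-deficient libraries of day 3 with a median of -1.12, and 9 of 13 members were called. As a list, these genes fell short with an estimated correlation (camera adjusted p = 0.473) and passed with fry (adjusted p = 0.00278). GC content and transcript length over the other genes predicted 0.0559 for them, so that bias is argued against. A single abundant transcript is argued against as well, because without COX1 the share of counts was 0.199 ± 0.0232% in Batf-deficient and 0.464 ± 0.0784% in wild-type libraries, the highest of the former (0.225%) lying below the lowest of the latter (0.387%). Differences in RNA extraction between samples were not tested and stay open beside a biological effect of genotype.

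Of the 10 splits of the 6 day 3 libraries into equal groups, the real split called 7820 genes and the highest other split 0, so 1 of them, the real split, called that many. With 10 splits the share cannot fall under 0.05. Every other split mixes the genotypes in both groups, so their difference adds to the spread there and the contrast in counts decides nothing.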

How the results depend on the processing

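The limit of at least 5 CPM at day 3, the scaling to T-cell identity genes, the slope over rising genes and the swaps of genotypes were tests chosen only after the results were seen. Over all alternatives, 14999 values of named genes kept the side of the threshold, 524 lost the call, 183 gained it and 22 reversed while called in either fit. For lists, 2321 kept the side of the threshold, 88 lost the call and 71 gained it. A value called in neither fit counts as kept even where its direction changed. A list that changed direction together with its call counts as lost or gained. The 22 reversals came with the scaling to T-cell identity genes, which moves all genes alike by -0.51 (genotypes at day 3), 0.054 (day 0), -0.41 and -0.97 (time in wild-type and Batf-deficient cells) and -0.56 (interaction), so they only mark genes that lay within that shift, and some were not called on one side. They were, for the genotypes at day 3, Eomes -0.45, Il2ra -0.37, Bhlhe40 -0.098, Ccnb2 -0.36, Pdk1 -0.10, Cox4i1 -0.31, Srebf2 -0.26, Zbtb7b -0.12, Fcer1g -0.054, Kdm5d -0.27, Uty -0.37, Eif2s3y -0.46 and Eif2b2 -0.11, in the change over time of Batf-deficient cells Eomes -0.58, Tcf7 -0.90, Klrg1 -0.41, Ddx21 -0.093 and Bop1 -0.24, and in the interaction Stat4 -0.15, Itgb2 -0.0035, Slc1a5 -0.20 and Srebf2 -0.16. That scaling holds the summed identity genes constant, although as a list they differed with the preset correlation for the genotypes at day 3, time in Batf-deficient cells and the interaction, so it does not decide directions. With an estimated correlation these list calls were lost (camera adjusted p = 0.112, 0.121 and 0.0931). Asking for 2-fold removes small changes by construction and left 1805 genes for the genotypes at day 3, 467 at day 0, 7957 for time in wild-type, 7424 for time in Batf-deficient cells and 1749 for the interaction. An adjusted p under 0.01 left 1706 at day 0. Testing only genes of at least 5 CPM at day 3 left fewer genes to call, 7808 for time in wild-type and 7682 in Batf-deficient cells, and removes genes that fell by construction, so the direction of change is not read from it. Leaving out each library gave 1590 to 3282 genes for the genotypes at day 0, 6996 to 7864 at day 3, 12009 to 13169 and 11954 to 13036 for time in wild-type and Batf-deficient cells, and 5134 to 6098 for the interaction. Where a group kept 1 sample, that sample was assumed to vary like the other groups. The slope was 1.02 with limma-voom, 1.02 over genes called in wild-type cells and 1.02 to 1.09 across left-out libraries; the cause was not tested. It was 0.782 over genes that rose and 0.843 over genes of at least 5 CPM at day 3, against 0.926 to 1.09 and 0.965 to 1.03 with the genotypes of each gene swapped at random, and 1.05 over all genes tested. The swaps make the genotypes alike by construction, so they test only the choice of genes and give no spread between libraries. Without a filter 38.8% of the called genes were higher at day 3, against 50.6%. The labels do not say whether replicate numbers pair the samples. No pairing was seen at day 3, where same-number residuals correlated at 0.03, -0.02 and 0.01. A block for the number gave 7843, 3202, 12679, 12634 and 6280 genes in the order of the comparisons and a slope of 1.04. The block also ended 5 list calls, of myeloid markers at day 0, of inhibitory receptors in Batf-deficient cells over time, of dendritic cell markers in wild-type cells over time and of chemokine receptors in both genotypes over time. Depth limits genes at or below 3 counts, 0.0413 to 0.0589 CPM.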

Other observations

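Chosen only after the results were seen were the genes in this part and the tests of other-cell RNA and library size.

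Some transcription factors and enzymes stood out among genes above 10 CPM at day 3. Maf, which encodes a transcription factor of the AP-1 superfamily, was at 3.61 ± 0.493 CPM in Batf-deficient and 30.4 ± 4.31 CPM in wild-type cells (SD, n = 3). Epas1, which encodes the hypoxia factor HIF-2 alpha, was at 9.72 ± 2.61 against 57.2 ± 3.86 CPM. Bcat1, which encodes an enzyme of branched-chain amino acid use, was at 9.71 ± 0.608 against 45.3 ± 6.22 CPM, and the protease inhibitor gene Ctla2a at 34.3 ± 7.41 against 187 ± 6.30 CPM. Ptpn13 and Emp1 had log2 fold changes of -3.35 and -2.68. Higher in Batf-deficient cells were the chemokine gene Ccl5, at 676 ± 8.74 against 119 ± 24.1 CPM, the RNA sensor gene Tlr7, at 47.5 ± 2.60 against 6.38 ± 1.68 CPM, and Nt5e, which encodes the ectoenzyme CD73, at 48.4 ± 3.21 against 9.997 ± 0.855 CPM.

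A few genes differed by a like amount at both days. Plac8 was higher by 1.57 at day 3 and 1.51 at day 0, Ms4a4c by 2.16 and 2.04, and Gbp10 by 2.29 and 2.64, while Mid1 was lower at -1.65 and -1.87. Across the genes called at both days, 969 of 1980 had the same sign, and the genotype differences of the 8900 genes called at either day correlated at r = 0.07 across genes.

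The day 0 libraries held abundant transcripts of other cell types although cells had been sorted by flow cytometry, which should remove those types. Marker genes were put in classes, of which those of neutrophils and acinar cells were picked after their ratios were seen. The median ratio of Batf-deficient to wild-type samples was 21.6 for neutrophils, 14.3 for pancreatic acinar cells, 2.24 for B cells and 2.03 for natural killer cells. It was 1.23 for erythroid cells, 0.749 for fibroblasts and 0.735 for splenic macrophages. Markers of splenic macrophages summed to 9387.6 CPM in wild-type and 7052.8 CPM in Batf-deficient samples. Over 67 genes of 6 marker lists fixed before, 14.8% of the variance of the genotype ratio at day 0 lay between lists (permutation p = 0.0668, mean of 7.52% with shuffled lists). The myeloid list mixes cell types, with S100a8 at 4.45 and C1qa at 0.01 (SD of its members 1.85), so the test decides nothing. Transcripts of other cell types were present in both genotypes of day 0. Genotype differences in the marker genes themselves are not read as differences between T cells. How far RNA of other cells accounts for the remaining genotype differences of day 0 stays open. The lowest day 0 level of myeloid markers was 58.3 times the highest of day 3. These levels are already scaled to library size, so as a test of library size this adds little to the pattern itself.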
